A study of Mus musculus with 9 samples.

How the data were processed

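Bulk RNA was profiled from B1-8hi B cells, which carry a rearranged heavy-chain gene that favours binding of the hapten NP, marked with GFP and transferred into wild-type mice. The recipients were immunized with NP-KLH and the cells came from lymph nodes 5 days later. The comparison was between 6 control libraries and 3 libraries of B cells in which Cre expressed from the CD23 locus deletes floxed Smarca5. Groups and replicate numbers were taken from the sample titles. Nothing in the labels says that the libraries of a group came from separate mice, so p-values measure the spread between these libraries, which may be technical.

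Libraries were made with a bulk form of MARS-seq, a method that sequences a tag near the 3' end of polyadenylated RNA, per the labels' protocols. The submitters' processing notes name cutadapt, STAR, HTSeq and the genome build mm10, with no versions. The gene annotation, the treatment of reads that map to several places and the use of molecular identifiers are not given in the sources used here. The deposited table holds raw counts per gene symbol, not normalized, per the file headers. It lists 10247 genes, and no gene has a highest count below 6. Immunoglobulin constant region genes and mitochondrially encoded genes were not analysed here, so CPM values and shares of counts are over totals without them, and the planned comparison of immunoglobulin transcripts and the settings without immunoglobulin genes were not run.

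Total counts ran from 1865814 to 4239429 in the controls and from 828041 to 1274757 in the knockout libraries. Floors cover counting error only, since reads may not be independent molecules. Intervals of medians are bootstrap intervals over genes. For a gene at 0 in every library of a group the floor was 3 counts over the group, which is 0.163 CPM (counts scaled to a common library total) in the controls and 1.10 CPM in the knockout libraries.

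Genes were kept with edgeR's filterByExpr, which left 8306. They were scaled with TMM factors and tested with edgeR 4.0.16 (glmQLFit with robust = TRUE, glmQLFTest) in R 4.3.3, with group as the only term. P-values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. A standard error (SE) is the fold change divided by the square root of the F statistic. Levels are TMM-scaled CPM as mean ± SD. Principal components used log2 CPM with a prior count of 2 for the 500 most variable genes. Library measures were compared with two-sided exact permutation tests over the 84 ways to split 9 libraries into 6 and 3, adjusted over 13 measures.

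A set of 30 gene lists was fixed before the data were examined, and 24 had at least 5 tested members. Lists were tested with camera (limma 3.58.1) on voom values with a preset inter-gene correlation of 0.01, then with an estimated correlation and with fry. Camera compares a list with all other genes. Fry asks whether a list's genes move one way on balance, without comparing it with other genes. The lists hold textbook members of B cell programmes, the cell cycle, metabolism, remodellers and other cell types, and none was chosen on these libraries.

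Named genes followed a rule. It took the ISWI list, the 12 called genes with the smallest p in each direction (mean CPM of at least 10 in a group, no overlap between groups, predicted genes left out), up to 4 members with the smallest p per list, and a set of B cell regulators fixed whatever their result. Some genes that the rule takes are not reported here. Genes outside the rule are said to be chosen after their values were seen.

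Gene symbols were matched to the GENCODE vM21 annotation of the same build, and 10190 of 10247 matched. For each gene, the last 500 transcript bases were cut into words of 50 bases. The share of words found in a transcript elsewhere in the genome marked genes whose reads can be shared with a copy. Values of genes with shared words are uncertain, because the counting of such reads is not known.

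The steps were tested on simulated counts for the same comparison, made from the real means and library sizes of 8076 genes with 200 changed. The edgeR test called 52.0% of the genes changed 2-fold and 14.1% of those changed 1.5-fold, and 4.35% of its calls were unchanged genes. The real comparison called 40.5% of the genes tested, a far larger share than was changed here. These rates may therefore not hold for it. No pair of control libraries agreed within sampling noise, since the lowest chi-square per gene of a pair was 1.94. The lowest pair of knockout libraries gave 2.51.

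Alternatives fixed before the data were examined were DESeq2 size factors, no TMM factor, no filter and a stricter filter (CPM of 10 in 3 libraries), DESeq2 1.42.0, voom with quality weights, each library left out, a replicate block, thinning to the smallest total, a fold threshold, fry and an estimated correlation, list members held by 1 list only, and 2000 genes in the principal components. Those chosen after seeing the data left out genes with shared 3' words, corrected for GC content, left out controls 5 and 6, compared subsets of libraries, or left out genes on X and Y.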

Results

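The libraries compared transferred B cells labelled as controls with B cells carrying a conditional knockout of Smarca5, an ATPase of the ISWI family of chromatin remodellers, 5 days after immunization. The question was how the transcripts of these transferred B cells differ between the groups. Bulk libraries cannot tell a change within each cell from a change in the mix of cells. Totals were 2972650 ± 938737 counts per library in the controls (SD, n = 6) and 980611 ± 254797 in the knockout group (SD, n = 3). The difference passed a two-sided exact permutation test (p = 0.0238, adjusted 0.0258). Genes detected averaged 10149.7 ± 72.3 and 9545 ± 267 (exact permutation p = 0.0119, the smallest that 84 splits allow, adjusted 0.0155). With all libraries thinned to the smallest total they averaged 9716.7 ± 90.9 and 9475 ± 152 (exact permutation p = 0.0238, adjusted 0.0258). The slope of log2 CPM on the GC content of 3' ends was -0.06 ± 0.05 per 10% in the controls and 0.11 ± 0.07 in the knockout libraries, and the 10 most abundant genes took 8.18% ± 0.409 and 10.6% ± 0.315 of counts (SD, exact permutation p = 0.0119 for each, adjusted 0.0155).

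Smarca5 (ENSMUSG00000031715, mm10 chromosome 8, 80698507 to 80739497, minus strand) was close to the detection limit. The controls held 33, 15, 17, 17, 1 and 3 counts, in order of number, and the knockout libraries 8, 0 and 0. Scaled to library totals, knockout 1 stood at 6.67 CPM, within the controls' range of 0.35 (control 5) to 8.83 CPM (control 3). The log2 fold change of Smarca5 was -0.80 ± 1.23 (SE), with an edgeR adjusted p of 0.647 and a two-sided exact permutation p of 0.214 on log2 CPM. The labels do not say which exons are deleted, and a 3' tag outside them would still be counted. The transcript therefore did not check the genotype labels. Without knockout 1 the fitted change was -6.62, a value that depends on the prior count because the other knockout libraries were at 0.

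The groups also differed in sex-linked transcripts, chosen after their values were seen. Xist, the RNA that silences 1 X chromosome in female cells, had no count in the 6 controls and averaged 24.5 ± 8.77 CPM (SD, n = 3) in the knockout libraries, at least 150.1-fold higher against the floor over the control group. The Y-linked gene Eif2s3y averaged 32.1 ± 16.8 CPM in the controls (SD, n = 6) and held 4, 0 and 0 counts in the knockout libraries. Kdm5d, also on Y, averaged 8.55 ± 1.01 CPM in the controls and held 0, 1 and 2 counts in the knockout libraries.

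The first principal component held 63.4% of the variance and separated the groups, with control 5 nearest to the knockout libraries. Spearman correlations ran from 0.934 to 0.983 between controls, from 0.937 to 0.956 between knockout libraries and from 0.850 to 0.900 between groups.

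**Figure D1:**
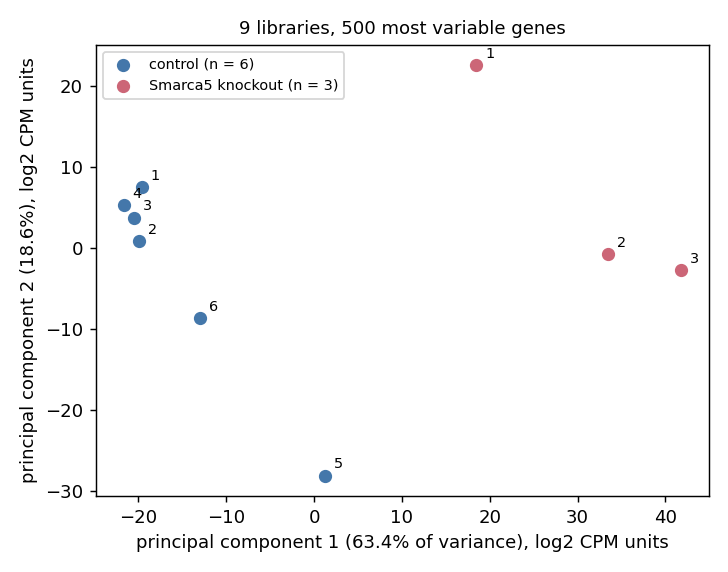
Principal components 1 and 2 (in log2 CPM units) of the 500 most variable genes, with each point a library labelled by its replicate number. The 6 controls lie at or below 1.24 on component 1 and the 3 knockout libraries at or above 18.5.

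Of 8306 genes tested, 1726 were higher and 1639 lower in the knockout libraries by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The 12 lower genes with the smallest p included H1f10, a linker histone (log2 fold change -4.68 ± 0.21, 286 ± 26.2 CPM in controls and 11.6 ± 4.96 in knockout libraries), and Anxa2, a calcium-dependent membrane-binding protein (-3.42 ± 0.18). The others were Apobec1, Rassf6, Pafah1b3, Rgs10, Ada, Uchl1, Polr2g, Eaf2, Cdkn3 and Basp1, from -4.68 for Rassf6 to -1.90 for Pafah1b3. The 12 higher genes included the chemokine Ccl22 (4.16 ± 0.15, 10.1 ± 2.09 CPM in controls and 186 ± 12.3 in knockout libraries) and the antigen receptor subunit Cd79a (2.53 ± 0.14). Others were Rpl19, Eno1, Rpl13, Rpl27a, Rpl35, Fau, Rpl37rt, Tma7 and Rpl17, from 1.56 for Rpl17 to 2.63 for Eno1. Many of these share 3' words with other genes, for example 81.6% of the words for Rpl19, and such values are uncertain. All 24 had edgeR adjusted p of at most 1.23e-07. Over all genes, 1618 lay higher and 1496 lower with no overlap between the groups' libraries, which chance gives for 2.38% of genes in the 2 directions together. Without the TMM factor, which moved the median of all genes from -0.0049 to -0.15, 1270 genes were higher and 2111 lower.

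Germinal centre genes were lower in the knockout libraries. Of 24 tested members of this list, 15 fell, 1 rose and 8 did not pass, and the counts adjusted over the list alone were 15 and 1. S1pr2, a receptor that confines B cells to germinal centres, had a log2 fold change of -3.56 ± 0.34 (SE, 258 ± 35.4 CPM in controls and 23.2 ± 18.7 in knockout libraries, edgeR adjusted p = 2.12e-05). Lower values were also found for Bcl6 (-1.42 ± 0.17), the transcription factor that germinal centre B cells require. Nuggc, Eaf2 and Basp1 were also lower (-2.90, -3.01 and -2.97). The member that rose was Lmo2, at 1.13, named after its value was seen. Fas (-0.90 ± 0.39, edgeR adjusted p = 0.0884) and Bach2 (-0.16 ± 0.20, 0.560) did not pass. In a minority of settings Fas did, among them edgeR without knockout 1 (-1.69, adjusted p = 0.00932) or control 6 (-1.03, 0.0231). It also passed edgeR after thinning to the smallest total (-1.12, adjusted p = 0.0199) and DESeq2 (-0.94, adjusted p = 0.0385). The list had a median log2 fold change of -1.04 and a camera adjusted p of 5.95e-06, and adjusted p = 0.168 with an estimated correlation. Without knockout 1 the median was -1.69.

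Plasma cell genes were lower as well, with 20 of 27 tested members down, 0 up and 7 not past the threshold. Adjusted over the list alone, 21 fell. Sdc1, the surface proteoglycan CD138 of plasma cells, fell by 3.42 (SE 0.45, edgeR adjusted p = 0.000126), from 66.4 ± 21.4 CPM in controls to 6.13 ± 0.872 in knockout libraries. Lower values were also found for Xbp1 (-1.49 ± 0.19), a transcription factor of secretory cells, Sec11c (-1.33 ± 0.18), a signal peptidase subunit, and Mzb1 (-2.08 ± 0.28), a chaperone of the endoplasmic reticulum. The regulators Prdm1 (-0.34 ± 0.49, edgeR adjusted p = 0.615) and Irf4 (-0.25 ± 0.22, 0.391) did not pass. Jchain, the joining chain of polymeric antibodies, did not pass either (-2.30 ± 1.25, 0.186) and varied between controls (214 ± 271 CPM), but passed with DESeq2 (-2.44, adjusted p = 0.0499). The list had a median of -1.49 and a camera adjusted p of 6.47e-09, and adjusted p = 0.303 with an estimated correlation. With controls 5 and 6 and knockouts 2 and 3 alone, fewer libraries, 7 of 27 fell and Mzb1 lost its call at a similar change (-1.81, edgeR adjusted p = 0.0994). The list stayed past camera in all 23 other camera settings with a preset correlation (highest adjusted p = 1.93e-05), of which 1 has 1 knockout library.

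Genes of the unfolded protein response shared 6 tested members with the plasma cell list. Of 25 tested, 18 fell, 1 rose and 6 did not pass, and adjusted over the list alone 20 fell and 1 rose. Sel1l and Herpud1, of endoplasmic reticulum-associated degradation, were lower (-2.12 ± 0.21 and -2.04 ± 0.20), as was the ubiquitin ligase gene Syvn1 (-0.92 ± 0.14). The camera adjusted p was 1.60e-06, and adjusted p = 0.322 with an estimated correlation. With controls 5 and 6 and knockouts 2 and 3 alone, fewer libraries, 7 of 25 fell. The list lost its camera call only with the estimated correlation, and its medians in the other settings ran from -1.65 to -0.98.

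Cell cycle genes fell together. In the S phase list 32 of 40 tested members fell, 1 rose and 7 did not pass (33 and 1 adjusted over the list alone), with a median of -1.18. Mcm2, Mcm3 and Mcm5, subunits of the replicative helicase, were lower (-1.54 ± 0.12, -1.06 ± 0.11 and -1.49 ± 0.15), as was Gins2 (-1.39 ± 0.14), which joins that helicase. In the G2/M list 38 of 48 fell, 0 rose and 10 did not pass (40 fell adjusted over the list alone), with a median of -1.43. Mki67, the proliferation marker Ki-67, fell by 1.88 (SE 0.16), and Ccnb2, Cdca8 and Birc5 stood at -1.65, -1.84 and -1.56. Camera gave adjusted p = 5.13e-12 for S phase and 8.36e-14 for G2/M, and adjusted p = 0.168 for each with an estimated correlation. The Cdk inhibitor Cdkn1a rose by 2.06 (SE 0.27, 12.7 ± 3.93 to 53.6 ± 17.7 CPM, edgeR adjusted p = 4.55e-05).

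**Figure D2:**
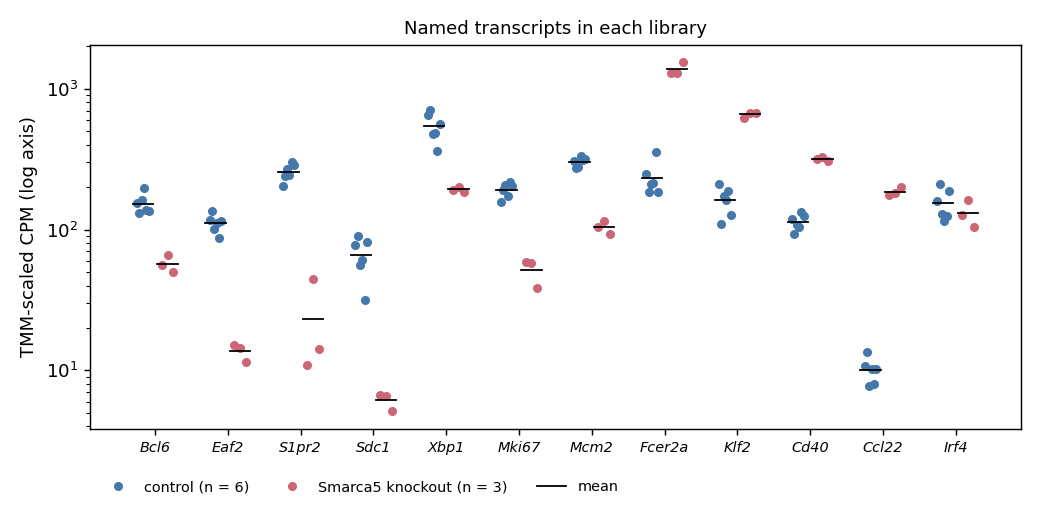
TMM-scaled CPM on a log axis for 12 transcripts, with each point a library, blue for the 6 controls and red for the 3 knockout libraries, and lines at the group means. All but Irf4 separate the groups, for example S1pr2 at 258 and 23.2 CPM and Fcer2a at 233 and 1375 CPM.

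Genes of naive follicular B cells were higher. Of 28 tested members, 16 rose, 1 fell and 11 did not pass, and the counts adjusted over the list alone were 16 and 1. Fcer2a, which encodes CD23, rose by 2.56 (SE 0.18, 233 ± 64.4 to 1375 ± 150.2 CPM, edgeR adjusted p = 1.14e-06). Cre is expressed from the CD23 locus in the knockout cells, and whether the controls carry it is not given here. An effect of the Cre allele on the Fcer2a value was therefore not tested. Klf2, a transcription factor of lymphocyte quiescence and migration, rose by 2.03 (SE 0.17), the survival gene Bcl2 by 1.80 (SE 0.18) and Rasgrp2 by 1.60 (SE 0.12). The member that fell was Vpreb3, at -0.55, named after its value was seen. The list had a median of 1.04 and a camera adjusted p of 4.77e-06, and adjusted p = 0.297 with an estimated correlation. Without knockout 1 the median was 0.69. The memory B list, which shares 6 tested members with it, had 6 members up, 4 down and 4 not past the threshold of 14 (adjusted over the list alone, the same counts), with a camera adjusted p of 0.126 and a fry adjusted p of 0.0138. In it, Zbtb32 fell by 1.64 and Hhex rose by 1.39.

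Antigen presentation and NF-kB target genes rose. Of 13 tested MHC class II genes, 10 rose, 0 fell and 3 did not pass (10 adjusted over the list alone). Cd74, the invariant chain, rose by 1.32 (SE 0.09, 11510 ± 1237 to 28777 ± 1926 CPM), and Ciita, the class II transactivator, by 1.25 (SE 0.17). Camera gave adjusted p = 3.84e-05, and adjusted p = 0.322 with an estimated correlation. Of 18 tested NF-kB targets, 11 rose, 0 fell and 7 did not pass (11 adjusted over the list alone), with Nfkb2 at 1.52 ± 0.12, the receptor Cd40 at 1.48 ± 0.12 and the inhibitor Nfkbia at 1.39 ± 0.15. Camera gave adjusted p = 2.62e-05, and adjusted p = 0.168 with an estimated correlation. Of 17 early response genes, 6 rose, 0 fell and 11 did not pass (5 adjusted over the list alone), with Ier2 at 1.61 ± 0.14 and Jun at 1.54 ± 0.22. Their camera adjusted p of 0.0246 became adjusted p = 0.322 with an estimated correlation, and the call was also lost without knockout 1 (0.0686), without knockout 3 (0.0525), without control 6 (0.0522) and with no filter (0.0517).

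Myc, a transcription factor of cell growth, rose from 42.1 ± 2.80 CPM (SD, n = 6) to 84.1 ± 22.9 (SD, n = 3, edgeR adjusted p = 0.000199). Of 37 tested genes of MYC and ribosome biogenesis, 17 rose, 2 fell and 18 did not pass (17 and 2 adjusted over the list alone), with Mybbp1a at 1.45 ± 0.10 and the nucleolar protein gene Nop56 at 1.72 ± 0.14, of whose 3' words 80.0% are shared. Camera gave adjusted p = 0.000314, and adjusted p = 0.297 with an estimated correlation. Of 71 cytosolic ribosomal protein genes, 54 rose, 0 fell and 17 did not pass (54 adjusted over the list alone), with a median of 0.73. Camera gave adjusted p = 1.19e-22, and adjusted p = 0.0872 with an estimated correlation. These genes took 19.7% ± 0.538 of counts in the controls (SD, n = 6) and 27.4% ± 0.255 in the knockout libraries (SD, n = 3, exact permutation p = 0.0119, adjusted 0.0155). Among the 16 tested without shared 3' words, 7 rose, 0 fell and the median was 0.20.

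In metabolism, 19 of 60 oxidative phosphorylation genes fell, 9 rose and 32 did not pass (20 and 9 adjusted over the list alone), with Atp5a1 at -0.81 ± 0.09 and Cox6b1 at -0.77 ± 0.10. The camera adjusted p was 0.0257, adjusted p = 0.5885 with an estimated correlation, and the call was lost without control 2 (0.0560) and with fry (0.0848). Without genes that share 3' words, 2 of 39 members rose and 14 fell. The list median of -0.12 became -0.20 without knockout 2, and without the TMM factor 29 fell, 7 rose and the median was -0.28. Of 19 cholesterol synthesis genes, 10 fell, 1 rose and 8 did not pass (10 and 2 adjusted over the list alone), with Sqle at -1.14 ± 0.22 and Stard4 at -1.08 ± 0.27. The camera adjusted p was 0.0178, adjusted p = 0.168 with an estimated correlation, and without knockout 1 it was 0.0686. Of 16 glycolysis genes, 8 rose, 4 fell and 4 did not pass (9 and 4 adjusted over the list alone), with a camera adjusted p of 0.0817 and, without knockout 3, of 0.0457, and with fry of 0.000261. Eno1 and Gapdh, which rose by 2.63 and 1.49, have 75.2% and 90.5% of their 3' words in other genes.

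**Figure D3:**
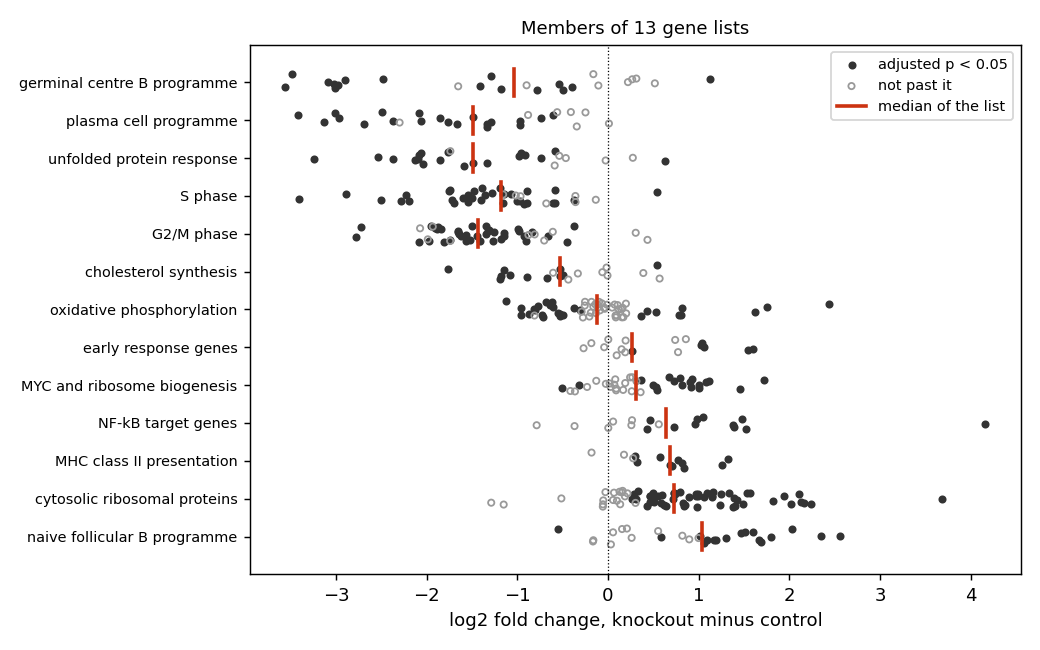
Log2 fold changes (knockout minus control) of the tested members of 13 gene lists past the camera threshold, with filled points for genes past the edgeR adjusted p threshold of 0.05, open points for the others and red lines at the list medians. Medians run from -1.49 in the plasma cell list to 1.04 in the naive follicular list.

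Remodeller genes moved both ways. Of 10 ISWI subunit genes, 2 rose, 1 fell and 7 did not pass (2 and 1 adjusted over the list alone), with a camera adjusted p of 0.906. Baz2a rose from 56.0 ± 6.02 to 113 ± 19.2 CPM (59.7% shared words) and Chrac1, a histone-fold subunit, by 0.75 (SE 0.15). Cecr2 fell by 2.29 (SE 0.64), a call lost without knockout 1 (edgeR adjusted p = 0.0578). Smarca5, Baz1a, Baz1b, Baz2b, Bptf, Pole3 and Rbbp7 did not pass. Of 13 other remodeller ATPase genes, 3 rose, 2 fell and 8 did not pass (3 and 2 adjusted over the list alone; camera adjusted p = 0.906). Smarca4, the BRG1 ATPase of SWI/SNF complexes, fell by 1.12 (SE 0.13), and Chd2 rose by 1.52 (SE 0.19). For both lists the camera direction was up while median and mean were below 0. Of 10 CTCF and cohesin genes, 3 fell, 0 rose and 7 did not pass (2 fell adjusted over the list alone; camera adjusted p = 0.194). The cohesin subunits Smc1a and Rad21 were lower (-0.82 ± 0.18 and -1.04 ± 0.24), with Rad21 at -1.57 without knockout 1. The third, Smc3 (-0.42), lost its call without controls 2, 3, 4 or 6 or knockouts 1 or 2, with edgeR adjusted p from 0.0526 to 0.154.

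Some markers of other cells also differed, but many had no counts listed. Those listed were 5 of 20 T cell, 14 of 20 myeloid and 1 of 12 NK cell markers. Of stromal and endothelial markers 3 of 14 were listed, and of erythroid markers 0 of 9. The few tested do not settle whether other cells were present. T cell markers had 4 tested members, too few for a list test, of which Thy1 rose by 2.13 (SE 0.28), Cd2 rose by 0.49, Lck fell by 0.62 and Lat did not pass (2 up and 1 down adjusted over the list alone). Of 10 myeloid markers, 2 rose, 4 fell and 4 did not pass (2 and 5 adjusted over the list alone; camera adjusted p = 0.645). Tyrobp rose by 2.57 (SE 0.20, 15.6 ± 4.29 to 92.6 ± 3.89 CPM) and Lyz2 by 2.52 (SE 0.34), while Cd68 fell by 1.15. Ccl5 was the 1 NK cell marker tested and rose by 2.40 (SE 0.46), and Pecam1 the 1 endothelial marker, which rose by 0.85 (SE 0.18). No erythroid marker was tested. Of 8 marginal zone markers, 1 rose, 3 fell and 4 did not pass (2 and 3 adjusted over the list alone; camera adjusted p = 0.906). Of 23 B cell identity genes, 7 rose, 4 fell and 12 did not pass (7 and 5 adjusted over the list alone; camera adjusted p = 0.708). Without the TMM factor 3 rose and 5 fell. With it, Pax5 did not pass (0.13 ± 0.26, edgeR adjusted p = 0.721), but did without control 5 (0.34, 0.0478).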

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

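The Dixon tests were fixed in advance. Of the tests of explanations below, those of donor sex and of the Smarca5 genotype were chosen only after the result was seen, and those with shared 3' words, GC content or transcript length after the data were seen but before their own results.

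Among the 6 controls, 141 quantities (129 named genes and 12 library measures) were tested for a library far from the rest, and 11 passed Dixon's 95% critical value for 6 samples. Chance flags about 1 in 20 such groups. Control 5 was the outlying library in 7 of them. It was low for Baz2b (ratio 0.855, 3.85 log2 CPM against 5.48 to 5.75 in the other controls), Rbbp7 (0.654), Tma7 (0.637), Cacna1s (0.662) and Prdm1 (0.674), and high for Rpl19 (0.661) and Pax5 (0.693, 8.50 log2 CPM against 7.33 to 7.69). Control 1 was low for Nuggc (0.660) and Mcm3 (0.816), control 2 was low for Fau (0.636), and control 6 was low for Rad21 (0.679).

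Germinal centre genes were lower in the knockout libraries, with a gap of 1.09 between the lowest control and the highest knockout mean log2 CPM of the list. With all libraries thinned to the smallest total, the list's median was -1.18. Thinning keeps each gene's expected share of its library, so it cannot decide whether depth, or the input behind it, is a cause. A GC content trend is not the whole cause, since the median was -0.88 after correction. The Smarca5 genotype and donor sex cannot be told apart, because 0 control libraries and all 3 knockout libraries held Xist counts. The Smarca5 genotype may account for the gap of 1.09, and the Smarca5 tag gave no independent sign of deletion.

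Ribosomal protein genes and genes with copies elsewhere were higher in the knockout libraries. A rise of ribosomal protein transcripts alone is argued against, because 167 genes of other kinds with over 30% shared 3' words had a median log2 fold change of 0.57. That median lay 0.59 above the median of 7464 genes with no shared word (95% bootstrap interval 0.43 to 0.84). Reads shared between gene copies, treated differently in the 2 groups, may therefore account for part of the rise. The 25 ribosomal protein genes with at most 10% shared words had a median of 0.22 (interval 0.07 to 0.45), so a smaller rise of these transcripts stays open, with the genotype and donor sex as untested causes.

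Genes that were low in controls 5 and 6 against the other controls tended to be low in knockouts 2 and 3 against knockout 1, with a correlation of 0.411 across 5790 genes, which are not independent replicates. GC content is argued against as the whole cause, because the correlation was 0.350 after correction for GC. Transcript length is argued against as the whole cause as well, with 0.410 after a correction that moved these differences by 0.09 in the controls and 0.03 in the knockout libraries (90th percentile of genes, log2 scale, against 0.17 and 0.30 for GC). Smarca5, with few counts, was low in the same libraries (0.35 and 0.88 CPM in controls 5 and 6, and 0 in knockouts 2 and 3). The labels give no batch and no group that follows this split. A shared batch could therefore not be tested, and no biological explanation was tested.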

How the results depend on the processing

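The GC correction, the removal of genes with shared 3' words or on X and Y, and the subsets of libraries were chosen only after the data were seen. No gene taken by the rule and no list changed direction while called. Genes outside the rule were not followed through the alternatives. Of 113 named genes called, 107 kept their call and sign in each of 21 alternatives that tested them, subsets of libraries aside. Many were named for a small p in the main fit, which favours keeping the call in refits of the same libraries. This share therefore does not measure how well the other calls hold. Requiring a log2 fold change above 1 left 688 higher and 734 lower genes, a limit set by the threshold itself. Controls 5 and 6 against knockouts 2 and 3 gave 771 higher and 779 lower genes among 7759, with fewer libraries, and 746 and 757 of them were called with all libraries. Without controls 5 and 6, the counts of genes higher in the knockout and genes lower in the knockout were 1863 and 1931.

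With an estimated correlation 0 lists passed camera, against 13 with the preset one. The medians do not depend on that choice, and germinal centre (-1.04, adjusted p = 0.168), plasma cell (-1.49, 0.303), naive follicular (1.04, 0.297), S phase (-1.18, 0.168) and G2/M (-1.43, 0.168) lists lost their calls. In the 23 other camera settings these 5 lists stayed past the threshold, with a highest adjusted p of 3.20e-05, and with fry the highest was 0.00497. The first principal component held 59.7% with 2000 genes.

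Leaving out each library gave 1428 to 1828 higher and 1404 to 1875 lower genes, both lowest without knockout 3 and highest without control 5. List calls ran from 11 to 14. Smarca5 stayed uncalled, from -6.62 to -0.33. Ranges of list medians were -1.69 to -1.01 (germinal centre), -1.63 to -1.40 (plasma cell), 0.69 to 1.24 (naive follicular), -1.43 to -1.11 (S phase) and -1.53 to -1.29 (G2/M).

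With the replicate number as a block, genes higher in the knockout numbered 1593 and genes lower in the knockout 1739. After each group's gene means were subtracted, the deviations of same-numbered libraries correlated at 0.269, 0.036 and -0.144, in order of number. No knockout library's deviations correlated best with those of the control of its own number, so these values gave no sign that the numbers pair the samples. Depth limits how many genes are tested. Thinned to the smallest total, 6784 genes were tested, with counts of 1416 for genes higher in the knockout and 1350 for genes lower in the knockout. Pseudocounts were not varied because the values are counts, and settings without immunoglobulin genes were not run.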

Other observations

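The comparison of X-linked genes and the choice of H1, receptor and zero-count genes were made only after the values were seen, and the tests of other splits were fixed in advance. The linker histone H1f10 was not alone in falling. Of 3 H1 genes tested, H1f10 (-4.68 ± 0.21) and H1f0 (-2.82 ± 0.34) were lower, H1f0 with 26.3 ± 5.84 to 3.71 ± 0.329 CPM (edgeR adjusted p = 2.01e-05), and H1f4 did not pass (0.03 ± 0.64, 0.983). Among single chemokine receptor genes, with no test of them as a group, Ccr7 rose by 1.69 (SE 0.21) and Cxcr5 by 0.92 (SE 0.13), while Cxcr3 was lower (-1.43 ± 0.18). Il21r, the receptor for the T cell cytokine IL-21, rose from 187 ± 31.8 to 375 ± 48.9 CPM. At the other extreme, 13 tested genes had no count in any knockout library. Pipox, a peroxisomal oxidase (20.8 ± 5.10 CPM in controls), was at least 19.0-fold lower against the floor over the knockout group, Baiap2l1 at least 10.4-fold and Vwa3b at least 6.11-fold.

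Genes of the p53 response, cell death and interferon did not pass camera as lists. Of 24 p53 targets, 7 rose, 1 fell and 16 did not pass (6 and 1 adjusted over the list alone; camera adjusted p = 0.126, 0.0457 without knockout 3, and fry adjusted p = 0.00181), with Phlda3 up by 2.58 (SE 0.22) beside Cdkn1a, and Gtse1, also a G2/M gene, down (-0.99). Of 14 BCL2 family genes, 3 rose, 4 fell and 7 did not pass (4 and 4 adjusted over the list alone; camera adjusted p = 0.906). The anti-apoptotic Bcl2 rose by 1.80, while the pro-apoptotic genes Bcl2l11 (83.3 ± 7.81 to 29.6 ± 5.39 CPM) and Bid (-1.18 ± 0.18) fell. Of 24 interferon response genes, 4 rose, 3 fell and 17 did not pass (4 and 3 adjusted over the list alone; camera adjusted p = 0.906), with Parp14 up by 1.17 and Isg20 down (-2.39 ± 0.41). The interferon list's median was -0.06 and its mean 0.04, with the camera direction down.

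Other splits of the 9 libraries into 6 and 3 did not give as many calls. Of 84 splits, 1 called at least 1726 higher genes, the real one, and the highest other split called 13. For lower genes 1 split reached 1639, and the highest other called 158, for control 5 with knockouts 2 and 3 as the smaller group. For both counts 1 of 84 is the smallest share this test can give, which argues against a chance labelling of these libraries. A chance difference between animals is not excluded, since the libraries of a group may not come from separate mice. Depth, sex and genotype all follow the real split.

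X-linked genes were called about as often as autosomal ones, 39.3% of 206 against 40.5% of 8063, a comparison made after the sex-linked transcripts were seen and not tested.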
